A study of Mus musculus with 12 samples.

How the data were processed

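Poly(A)-selected RNA from snap-frozen livers was sequenced from 12 libraries in 3 groups of 4, with 500 ng of Trizol-extracted RNA as input to a broad range library kit, per the labels' protocols. The submitters' processing notes name fastp, Salmon 1.10.3, DESeq2 and the mouse build GRCm39. The options, annotation release and strand setting are not given in the sources used here. One deposited table per library lists 147556 transcripts of 56065 genes, with gene symbols and biotypes. Its estimated counts are the expected number of reads per transcript, not normalized, per the file headers. Its TPM values are deposited as scaled within each library for transcript length and depth, per the file headers. The effective length is the transcript length less an allowance for fragment length, per the file headers. The reference at hand is of another build, so no genomic coordinates are printed.

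Expected counts were summed per gene and rounded to whole numbers. TPM and effective lengths were used only for the average transcript length of a gene in 1 alternative. Genes were filtered with edgeR's filterByExpr on the group (minimum count 10), and 13631 genes remained. Libraries were scaled with TMM factors, and CPM values are TMM-scaled. Each comparison was a contrast in 1 edgeR 4.0.16 quasi-likelihood model with a mean for each of the 3 groups and no covariate, fitted to all 12 libraries (9 residual degrees of freedom, common biological coefficient of variation 0.308). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic.

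Of 35 gene lists written before the data were examined, 33 had at least 5 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. The correlation was also estimated per list, and fry was run as a self-contained test. The lists for neutrophils (2 tested members) and neighbouring tissues (1) were not tested. Values of single libraries were compared between groups with exact two-sided permutation tests. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

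The genes named were chosen by a rule written before the data were examined. It takes the 4 largest increases and the 4 largest decreases of each comparison among protein-coding genes with a full symbol, an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the libraries of both groups. For MD vs CD and MD+CA vs MD it adds the 3 members with the smallest p of each of the 6 lists with the smallest camera p. Everywhere it adds 6 fixed genes, Ahr, Cyp1a1, Stc2, Cyp7a1, Col1a1 and Trem2. Some genes that the rule takes are not reported here. Other genes were named after their values were seen: the rest of the 12 genes changed in MD vs CD, list members where 5 or fewer passed, the examples among shared genes, the clock sets, and the sex-linked and sex-biased genes.

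The steps were tested on simulated counts for the 13631 genes with 200 genes changed, 50 each by 2, 4, 8 and 16 fold. For MD vs CD edgeR recovered 26, 80, 100 and 100% of them, for MD+CA vs MD 24, 86, 96 and 96%, and for MD+CA vs CD 36, 88, 98 and 100%. Of its calls 5.6, 6.2 and 4.7% were false in the 3 comparisons, against 14.8, 13.8 and 10.3% for DESeq2 and 5.7, 5.2 and 2.6% for limma voom. At this depth and spread a 2 fold change is thus missed more often than found. The simulated counts were drawn with edgeR's own estimates of spread and scaling and without libraries that stand apart. The shares of false calls therefore cannot rank the 3 methods on the real libraries. A list of 24 genes shifted by 2 fold was called by camera, with the preset and the estimated correlation, and by fry in all 3 comparisons. In MD+CA vs MD camera with the preset correlation and fry each made 1 false list call besides. The simulated genes varied independently, whereas this list, cholesterol synthesis and uptake, had an estimated correlation of 0.46 in the real libraries. The simulation therefore cannot tell how the list tests do when genes are correlated.

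Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2, limma voom with sample weights, no low-count filter, an average transcript length offset, protein-coding genes only, a model of only the 2 compared groups, the replicate number as a block, other prior counts (0.5 and 5) and leaving out each library in turn. A fragment length covariate, leaving out 3 libraries that stood apart and leaving out mitochondrial and ribosomal RNA genes were added after the data were seen. Pairs of libraries differed by more than sampling noise, so none was counted as a duplicate. Genes of near-identical families, such as Saa1 and Saa2, Tgtp1, Cyp3a41a and the Mup genes, share reads that the quantification divides between them, and their levels are uncertain. Without a stated strand setting, overlapping and antisense genes are uncertain too.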

Results

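Liver RNA was sequenced from mice in 3 groups, with 4 libraries in each. The first group, called CD here, received a control diet with 10 kcal% fat and matching sucrose. The second, MD, received a diet with 2% cholesterol, 20% of its energy from fructose and 40% from fat that is used to bring about metabolic dysfunction-associated steatohepatitis (MASH), with injections of vehicle. The third, MD+CA, received the same diet with injections of cinnabarinic acid at 12 mg/kg. Cinnabarinic acid is an endogenous product of tryptophan breakdown through the kynurenine pathway and a ligand of the aryl hydrocarbon receptor (AhR). Injections were given 3 times a week into the peritoneum, the vehicle was 0.2% DMSO in saline, and the diets began at 8 weeks of age and lasted 20 weeks. The mice carried floxed alleles of AhR. The labels do not say whether CD mice were injected, so MD and CD differ in diet and may differ in injection. The stated aim was to examine protection of the liver by cinnabarinic acid in MASH, which makes MD vs CD, MD+CA vs MD and MD+CA vs CD the comparisons of the design. The labels do not state outright that the 4 libraries of a group come from separate mice, and if they do not, p-values measure only the spread between these libraries.

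Each library held between 9089586 and 14492587 reads assigned to transcripts, with means of 12.58 ± 1.5 M in CD, 12.42 ± 2.04 M in MD and 10.57 ± 1.21 M in MD+CA (SD, n = 4). Of 56065 genes listed, 13631 had enough reads to be tested. Mitochondrially encoded genes took 10.93 ± 4.78% of assigned reads in MD, 6.205 ± 0.394% in CD and 6.29 ± 1.38% in MD+CA (SD, n = 4). The difference between MD and CD did not pass (exact permutation test, two-sided, p = 0.0857, adjusted p = 0.309 over 18 tests of library measures). MD replicate 2 had the largest share, 17.51%. The fragment length allowance is the bases that the quantification took off transcript lengths. It was 263 ± 14.5 in CD, 241.2 ± 18.8 in MD and 262 ± 23.5 in MD+CA (SD, n = 4). Its group differences did not pass either (exact permutation p = 0.171 for MD vs CD and 0.2 for MD+CA vs MD, two-sided). They were -21.8 and 20.8 bases, near or above the SDs. With 4 libraries per group the test does not show that the groups are alike. The number of genes with at least 1 read was higher in all 4 MD libraries than in the libraries of both other groups, by 771 on average against CD and 1150 against MD+CA (exact permutation p = 0.0286 for each, the smallest that 70 assignments allow, adjusted p = 0.257).

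**Figure D1:**
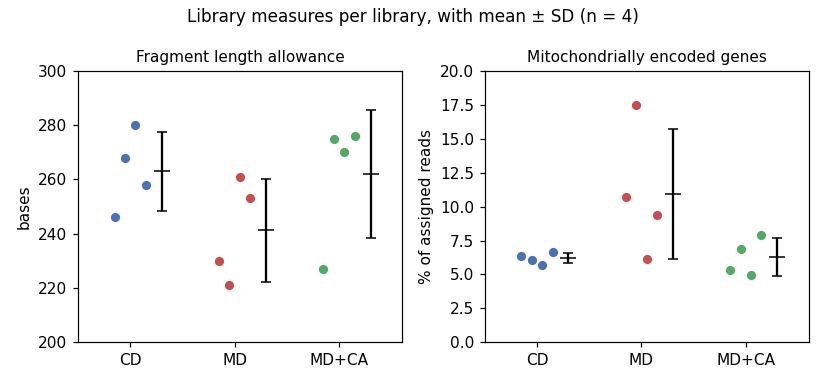
Fragment length allowance in bases (left, axis from 200 to 300) and reads from mitochondrially encoded genes in percent of assigned reads (right) for the 12 libraries by group. Points are libraries, and the tick with bars is the mean ± SD of 4 libraries; MD replicate 2 reached 17.51% in the right panel, and MD+CA replicate 1 had 227 bases against 270 to 276 in the rest of its group.

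The libraries were labelled as coming from male mice. Xist, the transcript that coats the inactive X chromosome, had between 5122 and 12865 reads in all 12 libraries. Ddx3y, Kdm5d, Uty and Eif2s3y, which lie on the Y chromosome, had 0 reads in all 12, which allows at most between 0.207 and 0.33 CPM in a library, counting error only. Cyp2b9, Cyp3a41a and Cyp2a4, genes of female-biased liver expression, had median levels of 327, 1940 and 698 CPM over the libraries. Mup20, Slco1a1, Elovl3 and Hsd3b5, genes of male-biased liver expression, had medians of 67.4, 4.7, 1.7 and 0.457 CPM, up to 211, 18.2, 9.39 and 6.08 in single libraries. Cyp3a41a has near-identical neighbours, so its level is uncertain.

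MD vs CD asks what the fat, fructose and cholesterol diet with vehicle changed. Genes that rose in MD included Gdf15, a stress-induced hormone of the TGF-beta family, Jun, a component of the AP-1 transcription factor, and Fitm1, which takes part in lipid droplet formation. Gdf15 rose from 3.9 ± 1.56 to 22.3 ± 10.6 CPM (SD, n = 4), a log2 fold change of 2.49 with a standard error (SE) of 0.38 and an adjusted p of 0.0392. Jun rose by 2.88 on the log2 scale (SE 0.49, adjusted p = 0.0469), and Fitm1 from 0.591 ± 0.481 to 7.6 ± 4.34 CPM (3.60, SE 0.63, adjusted p = 0.0486). Among genes that passed, Sema5b, a semaphorin, had the largest increase named, 4.12 (SE 0.64, adjusted p = 0.0392). Genes that fell included Smad9, a transducer of BMP signals, from 16.4 ± 3.95 to 2.58 ± 0.587 CPM (log2 fold change -2.67, SE 0.33, adjusted p = 0.01). G6pdx, the first enzyme of the pentose phosphate pathway and a source of NADPH, fell from 18.3 ± 7.84 to 4.81 ± 1.5 CPM (-1.93, SE 0.32, adjusted p = 0.0392). Pgap1, which remodels GPI anchors, and Nfxl1 fell by 1.32 and 1.30 on the log2 scale (SE 0.21 and 0.23, adjusted p = 0.0392 and 0.0493).

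In all, 12 of 13631 genes passed edgeR's quasi-likelihood test in MD vs CD, 6 higher and 6 lower, where 2719 genes (19.9%) had an unadjusted p under 0.05. The rest of the 12 were Ucp2 and Stmp1, which rose, and Rims4 and Gm15998, which fell. The count was 0 without CD replicate 1 or CD replicate 2, 1 without CD replicate 4, MD+CA replicate 2 or MD+CA replicate 4, 2 without MD replicate 1 or MD replicate 2, 5 without CD replicate 3 or MD replicate 4, and 26 without MD replicate 3. It was 6 with fragment length as a covariate, 2 with an offset for average transcript length, 35 with only both compared groups in the model, 374 with limma voom and sample weights, 481 without a low-count filter and 629 with DESeq2. Of the 12 fits with 1 library left out, the call of Smad9 held in 10 and those of the other 7 genes described above in 2 to 4.

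Of the lists for lipid metabolism, 2 shifted down and 2 up at a preset correlation, and Fitm1 was the only one of their members to pass the gene test. De novo lipogenesis was the list with the smallest p: its 20 tested members had a median log2 fold change of -1.01 (camera adjusted p = 1.79e-04, and adjusted p = 0.75 with an estimated correlation), and 16 of the 20 had a negative value. None of them passed over all genes with edgeR, 11 had an unadjusted p under 0.05, and 9 passed when adjusted over the list alone. Scd1, the delta-9 desaturase, had 10600 ± 3840 CPM in CD and 2530 ± 1870 in MD (log2 fold change -2.07, SE 0.50, adjusted p = 0.104). Acaca, acetyl-CoA carboxylase, had a value of -1.56 (SE 0.37, adjusted p = 0.104) and Pnpla3 of -3.47 (SE 0.75, adjusted p = 0.0888). Cholesterol synthesis and uptake also shifted down (median -0.40, adjusted p = 0.0105, and adjusted p = 0.82 with an estimated correlation). Here 0 of 24 members passed over all genes, 9 had an unadjusted p under 0.05, all of them lower, and 4 passed when adjusted over the list alone; Pmvk stood at -1.23 and Sc5d at -1.07 (adjusted p = 0.0888 and 0.118). Lipid droplets and fatty acid uptake shifted up (median 0.66, adjusted p = 3.76e-04, and adjusted p = 0.75 with an estimated correlation), with 1 of 18 members past the gene test (Fitm1) and 7 when adjusted over the list alone. Mogat1, a monoacylglycerol acyltransferase, had a value of 2.46 (SE 0.66, adjusted p = 0.115) and G0s2, an inhibitor of triglyceride lipase, of 1.52 (SE 0.41, adjusted p = 0.115). Fatty acid oxidation and PPARalpha targets shifted up by less (median 0.27, adjusted p = 0.02, and adjusted p = 0.84 with an estimated correlation), with 0 of 22 members past edgeR's test, 5 at an unadjusted p under 0.05 and 4 when adjusted over the list alone.

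Immediate early and heat shock genes shifted up in MD (median 1.47, adjusted p = 0.00198, and adjusted p = 0.75 with an estimated correlation), with 1 of 14 members past the gene test (Jun) and 8 when adjusted over the list alone. Fos had 1.78 ± 2.15 CPM in CD and 54.4 ± 49.7 in MD (log2 fold change 4.85, SE 0.96, adjusted p = 0.0765), and Btg2 a value of 3.17 (SE 0.65, adjusted p = 0.0785). Mitochondrially encoded genes shifted up as well (median 0.92, adjusted p = 0.00384, and adjusted p = 0.75 with an estimated correlation). None of the 13 passed edgeR's test over all genes, and 9 had an unadjusted p under 0.05 and passed when adjusted over the list alone. mt-Co3, mt-Nd4 and mt-Nd1 had values of 1.05, 1.32 and 1.05 (adjusted p = 0.115, 0.124 and 0.129). In MD replicates 1 to 4 the mean log2 CPM of the immediate early list was 5.42, 5.31, 5.11 and 3.89, against at most 4.27 in CD. Their mitochondrial shares were 10.68, 17.51, 6.16 and 9.37%, and their fragment length allowances 230, 221, 261 and 253 bases. Inflammatory cytokines and chemokines (median 0.47, adjusted p = 0.0111), extracellular matrix and fibrosis (0.32, adjusted p = 0.0226) and sinusoidal endothelial cell markers (0.35, adjusted p = 0.0226) shifted up, with adjusted p = 0.75, 0.82 and 0.75 with an estimated correlation. No member of these 3 lists passed edgeR's test over all genes; 2, 6 and 4 members had an unadjusted p under 0.05 (1 of the 6 matrix members was lower, the rest higher), and 0, 1 and 2 passed when adjusted over the list alone. Cxcl1 had a value of 1.55 (SE 0.52, adjusted p = 0.14), Cxcl16 of 0.38 and Icam1 of 0.53 (adjusted p = 0.243 and 0.252).

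That made 9 of 33 tested lists with a shift in MD vs CD, 7 up and 2 down, with a preset correlation between genes. With the correlation estimated per list none held. Some calls also ended with 1 library left out. Without MD replicate 3 these were cholesterol synthesis (-0.388), cytokines (0.391), matrix (0.319), endothelial markers (0.419) and fatty acid oxidation (0.175). Fatty acid oxidation and matrix also lost it without MD replicate 4 (0.167 and 0.221), these and endothelial markers without CD replicate 2 (0.144, 0.205 and 0.235), endothelial markers without CD replicate 3 (0.282) and fatty acid oxidation without CD replicate 1 (0.18). The number of shifted lists was 4 without MD replicate 3. Of the 35 possible splits of these 8 libraries into equal groups, 14 gave at least 9 shifted lists, so the number of lists does not set the real grouping apart.

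**Figure D2:**
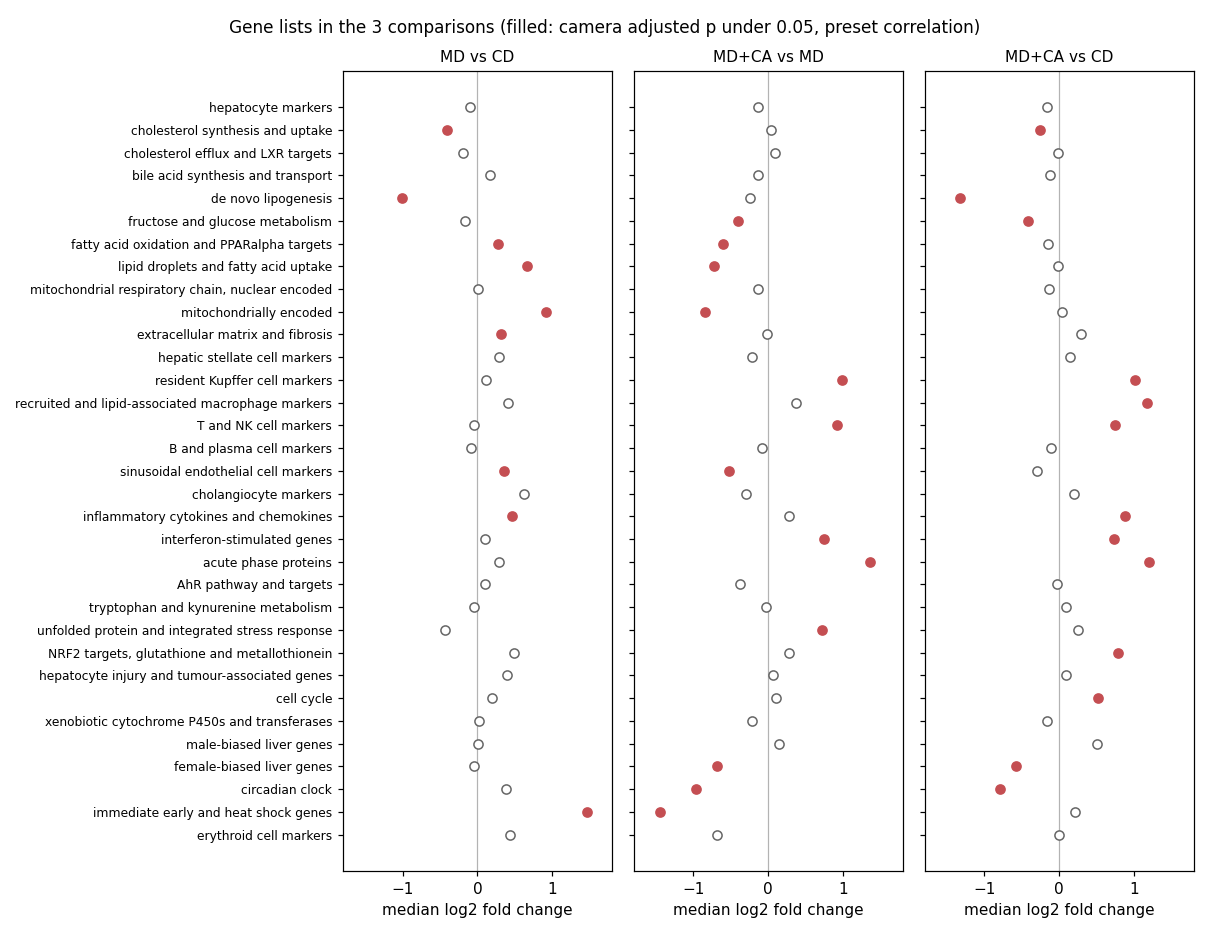
Median log2 fold change of the members of each of the 33 tested gene lists (vertical axis) in the 3 comparisons (panels, horizontal axis). Filled points are lists with a camera adjusted p under 0.05 at a preset correlation: 9 in MD vs CD, 13 in MD+CA vs MD and 13 in MD+CA vs CD, none of which held with an estimated correlation.

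MD+CA vs MD asks what cinnabarinic acid changed in mice on the MASH diet. Some macrophage and interferon genes rose in MD+CA. Marco, a scavenger receptor of macrophages, rose from 14.8 ± 11.2 to 128 ± 111 CPM (SD, n = 4), a log2 fold change of 3.12 (SE 0.61, adjusted p = 0.0198). Cd5l, a protein secreted by tissue macrophages, rose from 53.7 ± 12.2 to 168 ± 48.8 CPM (1.64, SE 0.26, adjusted p = 0.0105), and C1qa, a complement subunit, from 15.9 ± 5.27 to 32.9 ± 4.07 CPM (1.04, SE 0.22, adjusted p = 0.0245). Of 12 resident Kupffer cell markers, 4 rose (these and Vsig4), 8 passed when adjusted over the list alone and 11 had a positive value. The list shifted up with a median of 0.99 (adjusted p = 1.32e-05, adjusted p = 0.19 with an estimated correlation and 0.0027 with fry). The list of recruited and lipid-associated macrophage markers did not shift (median 0.37, adjusted p = 0.167), with 1 of 14 members higher and 5 when adjusted over the list alone. Interferon-stimulated genes shifted up (median 0.75, adjusted p = 3.36e-05, and adjusted p = 0.4 with an estimated correlation). Of its 23 members 3 rose and 13 passed when adjusted over the list alone. Cmpk2 rose by 1.48 (SE 0.26, adjusted p = 0.0147) and Oasl1 by 1.03 (SE 0.25, adjusted p = 0.0409). Tgtp1, an interferon-induced GTPase with a near-identical neighbour, had the largest increase named among genes that passed, 4.51 (SE 0.91, adjusted p = 0.0205), and MD+CA replicate 2 alone stood at 331 CPM against 14.8 to 26.6 in the rest of the group. Slc41a2, a magnesium transporter, rose by 3.06 (SE 0.55, adjusted p = 0.0171). T and NK cell markers shifted up (median 0.92, adjusted p = 0.0132, and adjusted p = 0.41 with an estimated correlation), with 0 of 5 tested members past edgeR's test, 2 at an unadjusted p under 0.05 and 0 when adjusted over the list alone; without MD+CA replicate 2 the shift did not pass, at a median of 0.458.

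Clock genes moved in both directions in MD+CA. Bmal1, which with Clock or Npas2 drives the molecular clock, rose from 1.28 ± 0.507 to 12.7 ± 3.85 CPM (SD, n = 4), a log2 fold change of 3.31 (SE 0.39, adjusted p = 0.00136). Per3 fell from 66 ± 16.7 to 5.51 ± 4.44 CPM (-3.56, SE 0.43, adjusted p = 0.00136), and Ciart, a repressor of Clock and Bmal1, from 18.6 ± 8.5 to 0.859 ± 0.676 CPM (-4.35, SE 0.55, adjusted p = 0.00162). Of 18 tested clock genes, 1 rose (Bmal1) and 9 fell, and 4 and 10 passed when adjusted over the list alone. The list shifted down at a median of -0.97 (adjusted p = 8.39e-04, adjusted p = 0.19 with an estimated correlation and 0.0027 with fry). The mean log2 CPM of 5 genes that peak with Bmal1 (Bmal1, Npas2, Clock, Nfil3 and Cry1) minus that of 10 genes driven by it (Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41) was -2.90 ± 0.69 in CD, -3.34 ± 0.36 in MD and 0.53 ± 1.29 in MD+CA (SD, n = 4). These sets were drawn up after the clock genes had been seen to change. The difference between MD+CA and MD was 3.87, and that between MD and CD was -0.44; since the sets were chosen on these samples, no p-value is given. All 4 MD+CA libraries, from -0.95 to 1.79, lay above all 8 others. The labels used here give no time of day for tissue collection. A different collection time therefore cannot be told apart from the compound for the other genes and lists that set MD+CA apart either.

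**Figure D3:**
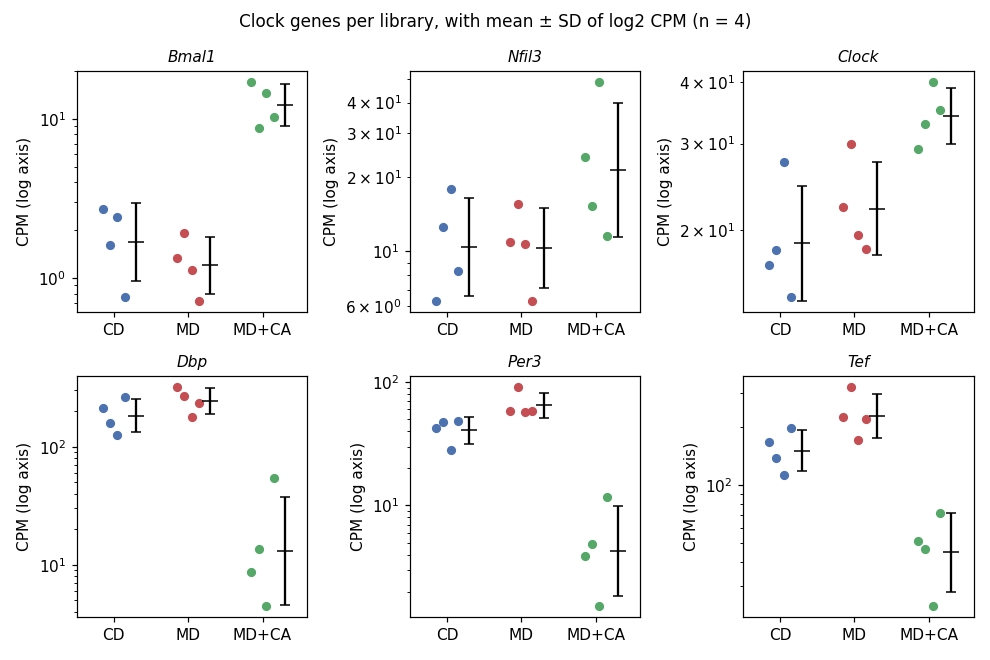
Levels of Bmal1, Nfil3, Clock, Dbp, Per3 and Tef in CPM on log axes for the 12 libraries by group. Points are libraries, and the tick with bars is the mean ± SD of log2 CPM of 4 libraries; Bmal1 was higher in MD+CA (12.7 against 1.28 CPM in MD) and Per3 lower (5.51 against 66 CPM).

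Of 14 tested immediate early and heat shock genes 7 fell in MD+CA. Fos fell from 54.4 ± 49.7 to 1.26 ± 0.743 CPM (log2 fold change -5.41, SE 1.02, adjusted p = 0.0178), and Egr1 from 263 ± 228 to 9.83 ± 3.98 CPM (-4.74, SE 0.94, adjusted p = 0.0198). When adjusted over the list alone 1 rose and 7 fell (median -1.45, adjusted p = 0.00897, and adjusted p = 0.4 with an estimated correlation). The list did not pass without MD replicate 3 or without MD+CA replicate 1, at medians of -1.487 and -1.561. Mitochondrially encoded genes shifted down (median -0.85, adjusted p = 8.39e-04, and adjusted p = 0.4 with an estimated correlation), with 0 of 13 past edgeR's test, 9 at an unadjusted p under 0.05 and 4 when adjusted over the list alone. mt-Co3, mt-Nd1 and mt-Nd4 had values of -0.99, -1.07 and -1.30 (adjusted p = 0.069, 0.0769 and 0.0799). Without MD replicate 2 the median of the mitochondrial list was -0.55. With fragment length as a covariate it was -0.68, and between -1.05 and -0.03 with 1 library left out besides. The mean log2 CPM of the immediate early list lay between 3.51 and 3.72 in MD+CA. Ppp1r3g, a regulator of glycogen synthesis, fell from 15.3 ± 13.3 to 0.317 ± 0.201 CPM (-5.50, SE 1.16, adjusted p = 0.0247).

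Of the metabolic lists, fatty acid oxidation, lipid droplets and fructose and glucose metabolism shifted down in MD+CA. De novo lipogenesis (median -0.25, adjusted p = 0.0942), cholesterol synthesis (0.04, adjusted p = 0.768), cholesterol efflux (0.09, adjusted p = 0.561) and the nuclear-encoded respiratory chain (-0.14, adjusted p = 0.479) did not. For cholesterol efflux the mean, -0.17, and the test pointed down, with 1 of 12 members lower and 4 when adjusted over the list alone. For cholesterol synthesis the mean, -0.03, and the test also pointed down, with 1 of 24 members lower. Fatty acid oxidation and PPARalpha targets had a median of -0.60 (adjusted p = 5.94e-04, and adjusted p = 0.54 with an estimated correlation), with 1 of 22 members lower and 3 when adjusted over the list alone. That member was Pex11a, a peroxisome division factor, which fell by 1.57 (SE 0.30, adjusted p = 0.0186). Fgf21, a hormone induced by fasting, had a value of -1.25 (SE 0.35, adjusted p = 0.064) and Acaa1b, a peroxisomal thiolase, of -1.21 (SE 0.39, adjusted p = 0.0897). Lipid droplets and fatty acid uptake had a median of -0.72 (adjusted p = 0.00138, and adjusted p = 0.4 with an estimated correlation). Of its 18 members 4 fell (Fitm1, G0s2, Pnpla2 and Mgll) and Lpl rose, and 9 and 1 did when adjusted over the list alone. Pnpla2 and Mgll encode lipases, so part of what moved in this list breaks fat down. Fructose and glucose metabolism shifted down (median -0.41, adjusted p = 0.00523, and adjusted p = 0.4 with an estimated correlation), with 2 of 17 members lower, the fructose transporter Slc2a5 and the liver glycogen synthase Gys2, and 3 when adjusted over the list alone. Sinusoidal endothelial markers had a median of -0.52 (adjusted p = 9.95e-04, and adjusted p = 0.4 with an estimated correlation), with 0 of 12 past edgeR's test, 6 at an unadjusted p under 0.05 and 4 when adjusted over the list alone. Female-biased liver genes shifted down (median -0.69, adjusted p = 8.39e-04, and adjusted p = 0.4 with an estimated correlation), with 3 of 15 lower (Acot3, Fmo2 and Cux2) and 5 when adjusted over the list alone.

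Acute phase proteins and the unfolded protein response shifted up. The acute phase list had a median of 1.36 (adjusted p = 5.94e-04, and adjusted p = 0.54 with an estimated correlation), with 0 of 18 members past edgeR's test, 14 at an unadjusted p under 0.05 and 12 when adjusted over the list alone. MD+CA replicate 3 carried much of it: Saa2, whose reads are shared with Saa1, stood at 14024 CPM there and at 34.4 to 112 in the rest of the group, and Orm2 at 2792 against 25.4 to 46.3. The list did not pass without MD+CA replicate 3, at a median of 0.382. Saa2, Fga and Orm2 had values of 6.30, 1.51 and 4.72 (SE 1.62, 0.40 and 1.25, adjusted p = 0.0511, 0.0534 and 0.0548). In the unfolded protein and integrated stress response 5 of 19 members rose (Hspa5, Hyou1, Manf, Creld2 and Dnajb9, chaperones and factors of the endoplasmic reticulum). The median was 0.72 (adjusted p = 0.00517, and adjusted p = 0.4 with an estimated correlation). When adjusted over the list alone 10 rose and 3 fell.

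In MD+CA vs MD 369 of 13631 genes passed edgeR's test, 145 higher and 224 lower, and 3157 (23.2%) had an unadjusted p under 0.05. With fragment length as a covariate 142 genes passed, 117 of them among the 369. The count was 99 with only both compared groups in the model, 183 with the length offset, 33 without 3 libraries that stood apart, 1017 without a low-count filter and 1214 with DESeq2. The share of higher genes, 145 of 369, was 49.8% without a filter and 48.8% with DESeq2, and at an unadjusted p under 0.05 1578 genes were higher and 1579 lower. Of the 35 splits of these 8 libraries another one called more genes, 382. It set MD replicates 1, 2 and 4 and MD+CA replicate 1, with 221 to 253 bases of fragment length allowance, against MD replicate 3 and MD+CA replicates 2, 3 and 4, with 261 to 276. The number of genes therefore does not set the real grouping apart from one that follows fragment length. The count was 233 without CD replicate 1, 109 without MD replicate 1, 130 without MD replicate 2, 963 without MD replicate 3 and 170 without MD replicate 4. It was 764 without MD+CA replicate 1, 119 without MD+CA replicate 2 and 129 without MD+CA replicate 3. The calls of Cd5l, Cmpk2, Slc41a2, Bmal1, Per3 and Ciart held in all 12 fits with 1 library left out, those of Fos and Pex11a in 11, of Tgtp1 and C1qa in 9, of Marco and Egr1 in 8, of Ppp1r3g in 7 and of Oasl1 in 2. Of 33 lists 13 shifted, 5 up and 8 down, none with an estimated correlation, and 10 of the 35 splits gave as many.

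**Figure D4:**
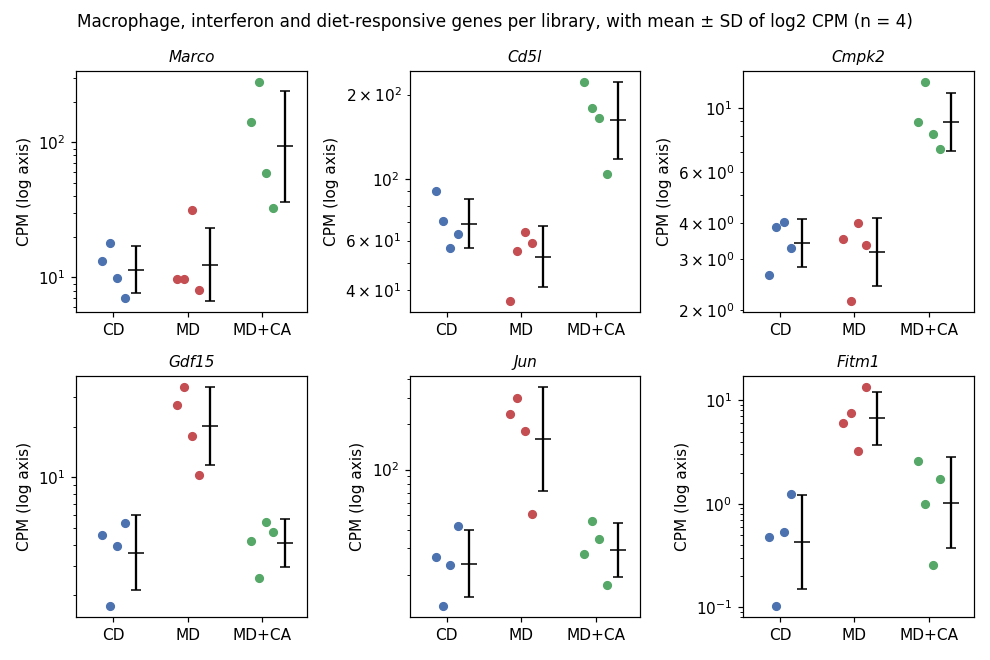
Levels of Marco, Cd5l, Cmpk2, Gdf15, Jun and Fitm1 in CPM on log axes for the 12 libraries by group. Points are libraries, and the tick with bars is the mean ± SD of log2 CPM of 4 libraries; Marco, Cd5l and Cmpk2 were higher in MD+CA, and Gdf15, Jun and Fitm1 were higher in MD than in both other groups.

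MD+CA vs CD asks what set treated mice on the MASH diet apart from mice on the control diet. Loxl4, a lysyl oxidase that cross-links collagen, rose from 0.449 ± 0.288 to 5.5 ± 3.86 CPM (SD, n = 4), a log2 fold change of 3.53 (SE 0.57, adjusted p = 0.0135). Marco rose by 3.42 (SE 0.62, adjusted p = 0.0307), Bmal1 by 2.75 (SE 0.38, adjusted p = 0.00783) and Saa3, a serum amyloid made by macrophages, by 2.46 (SE 0.35, adjusted p = 0.00902). Lepr, the leptin receptor, fell from 50.9 ± 23 to 5.13 ± 4.34 CPM (-3.34, SE 0.55, adjusted p = 0.0154). Ppp1r3g (-6.06, SE 1.17, adjusted p = 0.0334), Dbp (-3.23, SE 0.59, adjusted p = 0.0307) and Ciart (-2.90, SE 0.55, adjusted p = 0.0315) fell as well. Dbp is a transcription factor whose level follows the clock.

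De novo lipogenesis had the smallest list p here too (median -1.33, adjusted p = 7.83e-13, and adjusted p = 0.097 with an estimated correlation). Of its 20 members 1 fell, the elongase Elovl6, and 12 fell when adjusted over the list alone. Interferon-stimulated genes (median 0.74, adjusted p = 7.65e-12, and adjusted p = 0.078 with an estimated correlation) had 1 of 23 members higher, Cmpk2, and 14 when adjusted over the list alone. Resident Kupffer cell markers (median 1.02, adjusted p = 6.92e-10, and adjusted p = 0.057 with an estimated correlation) had 3 of 12 higher, Cd5l, Marco and Il18bp, and 8 when adjusted over the list alone. Recruited and lipid-associated macrophage markers (median 1.18, adjusted p = 2.24e-04, and adjusted p = 0.078 with an estimated correlation) had 1 of 14 higher, Cd68, and 8 higher and 2 lower when adjusted over the list alone. Cytokines and chemokines shifted up (median 0.88, adjusted p = 1.66e-06, and adjusted p = 0.078 with an estimated correlation), with 0 of 14 past edgeR's test, 8 at an unadjusted p under 0.05 and 8 when adjusted over the list alone. Clock genes shifted down (median -0.79, adjusted p = 1.6e-04, and adjusted p = 0.078 with an estimated correlation), with 1 higher and 4 lower of 18, and 5 and 11 when adjusted over the list alone. Fructose and glucose metabolism (median -0.41, adjusted p = 3.95e-06, and adjusted p = 0.08 with an estimated correlation) had 2 of 17 lower and 3 when adjusted over the list alone. Cholesterol synthesis (median -0.25, adjusted p = 5.1e-05, and adjusted p = 0.48 with an estimated correlation) had 0 of 24 past edgeR's test, 6 at an unadjusted p under 0.05 and 5 when adjusted over the list alone. Lists that shifted in MD+CA vs MD did not all shift against CD. Lipid droplets (median -0.01, camera adjusted p = 0.757), fatty acid oxidation (-0.15, 0.11) and endothelial markers (-0.3, 0.214) did not. Nor did mitochondrially encoded genes (0.04, 0.646), immediate early genes (0.21, 0.646) or the unfolded protein response (0.25, 0.136). That does not show that these lists were alike in both groups.

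Of 13631 genes 72 passed edgeR's test in MD+CA vs CD, 30 higher and 42 lower, and 1436 (10.5%) had an unadjusted p under 0.05. The count was 20, 23 and 17 without CD replicates 1, 2 and 4, 45 and 124 without MD replicates 1 and 2, and 31, 28, 37 and 169 without MD+CA replicates 1, 2, 3 and 4. It was 8 without the 3 libraries that stood apart, 34 with the length offset, 46 with only both compared groups in the model, 121 with protein-coding genes, 164 with fragment length as a covariate, 191 with voom, 334 with DESeq2 and 390 without a filter. The share of higher genes, 30 of 72, was 57.1% with voom, 54.5% with DESeq2 and 61.5% without a filter. The calls of Bmal1 and Saa3 held in all 12 fits with 1 library left out, that of Lepr in 11, of Loxl4 in 10, of Dbp and Ciart in 7 and of Marco and Ppp1r3g in 6. Of 33 lists 13 shifted, 8 up and 5 down, and 8 of the 35 splits gave as many.

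Of the 12 genes changed in MD vs CD, 7 also changed in MD+CA vs MD, all in the opposite direction. Fitm1, Gdf15, Sema5b, Jun and Stmp1 rose in MD vs CD and fell in MD+CA vs MD, and Nfxl1 and Gm15998 fell and then rose. Gdf15 stood at 3.9 ± 1.56, 22.3 ± 10.6 and 4.24 ± 1.24 CPM in CD, MD and MD+CA (SD, n = 4). Smad9 and G6pdx were lower than in CD in both diet groups. Independent lists of these sizes would share 0.0986 genes higher in MD and lower in MD+CA, and 0.0638 lower and then higher. Both comparisons use the same MD libraries, which alone push the 2 fold changes apart. In 20 simulations of unchanged groups with shared libraries no gene reversed. With the real MD libraries halved, 2 for each comparison, 0.5 genes reversed on average (0 to 3 over 6 halvings). In the same direction 0.333 genes moved (0 to 2). The halved comparisons called 0 to 1364 and 6 to 1771 genes, so these counts are not directly comparable with the 7. The simulations hold no real change and none of the structure between the real libraries. Few genes can pass in them, so they cannot tell how many of the 7 come from sharing libraries. The split that follows fragment length, described above, gave 58 reversed genes in the larger of its 2 labellings. The real grouping gave 7 as labelled and 43 with MD and MD+CA swapped, so 58 and 7 were not counted alike. The covariance of the fold changes across genes was -0.255, against -0.075 in the simulations, a difference of -0.18, and the correlation was -0.645 against -0.497. With separate MD libraries the covariance was -0.168 (range -0.204 to -0.122 over 6 halvings). On log CPM the covariance was -0.224 with shared MD libraries and -0.149 with separate ones (range -0.179 to -0.11 over 6 halvings). Genes are not independent replicates, so no p-value is given. The reversal count was 0 without CD replicate 1, 2 or 4 or MD+CA replicate 2 or 4, 1 without MD replicate 1 or 2, 2 without CD replicate 3 or MD+CA replicate 3, 4 without MD replicate 4 and 21 without MD replicate 3. It was 0 with the transcript length offset and without the 3 libraries that stood apart, 3 with fragment length as a covariate, 4 with only both compared groups in the model, 75 with voom, 225 without a low-count filter and 273 with DESeq2.

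MD+CA vs MD and MD+CA vs CD shared 43 genes changed in the same direction and 0 in opposite directions. The 15 shared increases, against 0.319 for independent lists, included the macrophage genes Marco, Cd5l, Csf1r, Aif1 and Mpeg1. The 28 shared decreases, against 0.69, included the clock genes Per3, Tef, Ciart and Dbp and the metabolic genes Slc2a5 and Gys2. Unchanged groups simulated with the shared MD+CA libraries gave 0.05 shared genes on average. These simulations hold no real change and none of the structure between the real libraries, so few genes can pass in them. Their 0.05 therefore cannot tell how many of the 43 come from sharing libraries. With the real MD+CA libraries halved, so with fewer libraries for each comparison, 7.167 genes were shared on average (0 to 15 over 6 halvings). The covariance was 0.176, against 0.077 simulated, a difference of 0.098, and 0.071 with separate libraries (0.002 to 0.133). The correlation, 0.503, did not exceed the simulated 0.507 and was 0.156 with separate libraries.

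The genes fixed in advance for the AhR pathway, bile acids, collagen and lipid-associated macrophages did not pass in any comparison. Ahr stood at 22.8 ± 4.12, 30.9 ± 5.52 and 23.2 ± 7.93 CPM in CD, MD and MD+CA (SD, n = 4; log2 fold change 0.44 for MD vs CD, adjusted p = 0.324, and -0.41 for MD+CA vs MD, adjusted p = 0.329). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had values of 0.60 and -0.66 (adjusted p = 0.42 and 0.349), and Col1a1 of 1.20 and -0.60 (adjusted p = 0.149 and 0.389). In MD+CA vs CD the values of Ahr, Cyp7a1 and Col1a1 were 0.03, -0.06 and 0.60 (adjusted p = 0.992, 0.991 and 0.733). Cyp1a1, a target of AhR, had 9, 14 and 5 reads in all in CD, MD and MD+CA, Stc2 had 21, 34 and 14, and Trem2 had 7, 21 and 27. All 3 were below the count filter and were not tested, and at such counts only a large rise would show.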

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

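The cell type, collection time, sex and MD replicate 2 tests below were chosen after the results they measure were seen; the fragment length and ribosomal RNA tests were added once the data had been seen, but before their own results, and the counts of splits were fixed before theirs. How far the ribosomal RNA test moves other genes was measured after its result was seen. Single libraries stood apart from the other 3 of their group, by the gap divided by the range, in 15 of 177 checks over 53 genes and 6 library measures, where chance gives about 8.85, or 1 in 20.

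Clock genes in MD+CA are the first pattern. A lower share of hepatocytes would move clock genes the same way. Both sets of clock genes moved apart by 3.87 log2 units between MD+CA and MD, with every MD+CA library above every MD library. They were drawn up after these genes were seen to change, so their choice favours such a gap, and it decides nothing here. In the clock list fixed in advance, 4 of 18 genes rose and 10 fell in MD+CA vs MD when adjusted over the list alone. These opposite directions argue against such a mixture as the whole cause. For fragment length, the bound written beforehand was that at least 5 of the 10 clock genes called would stay called with the covariate. With it 6 did, which meets the bound. Leaving out 1 library besides gave between 2 and 9, against 5 to 10 without the covariate, so fewer libraries alone lower this count. Given this spread, fragment length cannot be told apart from the grouping by that test. A test of size, tried afterwards because the first was undecided, is therefore given only as a description: the median absolute log2 fold change was 2.15 with the covariate and 2.13 without, and the difference between the sets was 4.07 (SE 0.71) and 3.87 (SE 0.61). MD+CA and CD had like fragment length allowances, 262 ± 23.5 and 263 ± 14.5 bases (SD, n = 4). Their set differences were 0.53 ± 1.29 and -2.90 ± 0.69 (SD, n = 4). These values, looked at afterwards, argue against fragment length as the whole cause of that difference. All 4 MD+CA libraries lay above the other 8. A different time of day at collection and an effect of the compound on the clock therefore cannot be told apart without collection times. Both may account for the pattern.

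Sex-linked transcripts are the second. All 12 libraries had at least 5122 Xist reads and 0 reads on 4 Y-linked genes, as livers from female animals would give, against the male label. All 4 of those genes have entries in the tables, which argues against transcripts missing from the index. A wrong sex label is a candidate explanation for all 3 groups alike, and no biological explanation was tested.

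Immediate early and mitochondrial transcripts in MD are the third. Without 83 mitochondrial and ribosomal RNA genes the immediate early median stayed at 1.47, and at 1.24 or more with 1 library left out besides. Leaving these genes out moved no other gene by over 0.018 log2 units, far less than 1.47. These values argue against such RNAs taking a share of the counts as the source of the immediate early shift. With fragment length as a covariate the immediate early median was 0.97 (0.57 to 1.41) against 1.47. The mitochondrial median was 0.69 (0.38 to 1.05) against 0.92. Fragment length, as a sign of RNA handling, and the diet therefore cannot be told apart. Without MD replicate 2 the medians were 1.34 (0.59 to 1.69) and 0.55 (0.36 to 0.8), so by the medians that library stays open as a source. Forms of this test without the spread, tried first, and by the levels of the other MD libraries, tried last, had excluded it. They were withdrawn as tests because they were picked with the values in view. By level, 2 of the other 3 MD libraries lay above all 4 CD libraries in each list. For the immediate early genes these 2 stood at 5.42 and 5.11, against at most 4.27 in CD. MD replicate 2 stood at 5.31, and MD replicate 4, at 3.89, lay within CD. These levels argue against MD replicate 2 as the only source of the immediate early shift. How much it adds stays open. 

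Other splits of the same libraries were counted for each result. For MD vs CD only 1 of 35 splits, the real one, gave 12 genes and the highest other gave 1. For MD+CA vs CD only the real one gave 72 and the highest other 10. The real grouping thus gave the most genes at 1 of 35, the smallest share that the test allows. The share is not corrected for the other counts tested, so it argues against a chance split only for each count taken alone. For MD+CA vs MD 2 of 35 gave as many as 369, the highest other 382, and chance is not excluded; that other split follows fragment length, and with the covariate 142 genes were called. For the lists 14 of 35 splits gave at least 9 in MD vs CD (highest other 13), 10 gave at least 13 in MD+CA vs MD (18) and 8 gave at least 13 in MD+CA vs CD (16), so chance is not excluded. For the reversal 2 of 35 gave at least 7 genes, the highest other 58, from the same split by fragment length. Each other split was counted in the larger of its 2 labellings, but the real one only as labelled. Swapped, the real one gives 43, so 58 and 7 are unlike counts. Chance is not excluded.

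Among genes, MD replicate 2 stood apart for Pgap1 (6.31 CPM, others 11.2 to 11.8) and Per3 (91.1, others 56.8 to 58.2). MD replicate 4 did for Mogat1 (5.01, others 0.916 to 1.2), MD replicate 1 for Tgtp1 (6.52, others 3.53 to 3.67) and MD replicate 3 for Marco (31.5, others 8.04 to 9.77). In MD+CA, replicate 2 stood apart for Tgtp1 (331, others 14.8 to 26.6), replicate 4 for Sc5d (649, others 325 to 348), and replicate 3 for Saa2 (14024, others 34.4 to 112) and Orm2 (2792, others 25.4 to 46.3). In CD, replicate 4 did for Ppp1r3g (69.0, others 3.76 to 13.2) and replicate 1 for Loxl4 (0.878, others 0.268 to 0.348). Among library measures, MD+CA replicate 1 had a fragment length allowance of 227 bases (others 270 to 276), and MD+CA replicate 3 had 17419 genes with a read (others 18798 to 18907). CD replicate 1 had 3.65% of reads on retained introns (others 3.18 to 3.26%), and CD replicate 2 had 7.15% on ribosomal RNA transcripts (others 0.933 to 1.39%).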

How the results depend on the processing

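Alternatives chosen after seeing the data were 3 libraries left out together, the fragment length covariate, mitochondrial and ribosomal RNA genes left out, and single libraries left out for the covariance; the rest were chosen before. Counts are given in the order MD vs CD, MD+CA vs MD, MD+CA vs CD and reversal, whose main values are 12, 369, 72 and 7. RLE and upper-quartile scaling and leaving out mitochondrial and ribosomal RNA genes kept all 4 within 1.5 times; upper-quartile scaling moved the median of all genes in MD vs CD to 0.11. DESeq2 gave 629, 1214, 334 and 273, and no low-count filter 481, 1017, 390 and 225. Voom with sample weights gave 374, 408, 191 and 75, the transcript length offset 2, 183, 34 and 0, only the 2 groups compared 35, 99, 46 and 4, and protein-coding genes only 13, 479, 121 and 6. The fragment length covariate gave 6, 142, 164 and 3. Without CD replicate 2, MD replicate 2 and MD+CA replicate 3, which stood apart, the counts were 0, 33, 8 and 0 (1292 genes in MD vs CD at an unadjusted p under 0.05), with fewer samples. Leaving out 1 library gave 0 to 26, 109 to 963, 17 to 169 and 0 to 21; the MD vs CD count was 0 without CD replicates 1 and 2, with 2326 and 1724 genes at an unadjusted p under 0.05. Apart from sample number, the cause was not tested.

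Shifted lists, 9, 13 and 13, fell to 0, 0 and 0 with an estimated correlation and to 0, 2 and 9 with fry, and ranged from 4 to 12, 12 to 17 and 10 to 16 with 1 library left out. With fry those in MD+CA vs MD were resident Kupffer cell markers and clock genes (fry adjusted p = 0.0027 for each). In MD+CA vs CD they were Kupffer cell (0.0049) and recruited macrophage markers (0.013), cytokines, interferon-stimulated and clock genes (0.014 for each). De novo lipogenesis, fructose and glucose metabolism, female-biased genes and cholesterol efflux, which camera did not call, followed (0.025 for each). The split-library covariance of fold changes, -0.149, was -0.092 without a filter and ranged from -0.243 to -0.098 with 1 library left out. The replicate number as a block gave 12, 664, 154 and 7. The library of the same number was the best of 4 partners in 9 of 12 cases, more often than chance would give. The correlations ran from -0.08 to 0.35, not all over 0.1. The labels state no pairing, so the numbers were not taken as pairs, but a batch shared by libraries of the same number is not excluded. The log2 fold change of Ahr, MD+CA vs CD, never past the test, turned from 0.03 to -0.004 with voom, -0.015 with the length offset, -0.011 with the block and -0.007 without the 3 libraries. With 1 library left out it ranged from -0.147 to 0.216, and was negative without CD replicates 1 and 2 (-0.02 and -0.056) and MD+CA replicates 2 and 4 (-0.072 and -0.147). The log2 fold change of Cyp7a1, MD+CA vs CD, also never past the test, ranged from -0.546 to 0.177, and was positive without CD replicate 2 (0.177) and MD+CA replicates 1 and 4 (0.118 and 0.137). Of the other values for named genes 1265 kept their direction and side of the threshold, 61 passed it and 190 lost it; of those for lists 607 kept it and 91 lost it. DESeq2 gave no adjusted p for 3 named values. Depth hides small changes in genes with few reads, such as Cyp1a1, Stc2 and Trem2.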

Other observations

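No test in this part was chosen after its result was seen. Several gene groups fixed in advance for the AhR and liver cell types did not shift. AhR pathway and targets had a median log2 fold change of 0.10 in MD vs CD and -0.38 in MD+CA vs MD (camera adjusted p = 0.631 and 0.25). Tryptophan and kynurenine metabolism had -0.04 and -0.03 (adjusted p = 0.56 and 0.612; in MD+CA vs MD the mean, 0.15, and the test pointed up). Hepatocyte markers had -0.10 and -0.13 (adjusted p = 0.254 and 0.804; in MD+CA vs MD the mean, 0.09, and the test pointed up). Xenobiotic cytochrome P450s and transferases had 0.02 and -0.22 (adjusted p = 0.963 and 0.174), and hepatic stellate cell markers 0.29 and -0.22 (adjusted p = 0.56 and 0.595). Extracellular matrix genes, which shifted up in MD vs CD (adjusted p = 0.0226, and adjusted p = 0.82 with an estimated correlation), had a median of -0.02 in MD+CA vs MD (adjusted p = 0.325). Bile acid synthesis and transport had 0.17 and -0.13 (adjusted p = 0.56 and 0.0942).

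In MD+CA vs CD 5 lists not described above shifted. Acute phase proteins had a median of 1.20 (adjusted p = 1.48e-07, and adjusted p = 0.37 with an estimated correlation), female-biased liver genes -0.58 (1.66e-06 and 0.08), T and NK cell markers 0.75 (0.0167 and 0.41), NRF2 targets 0.79 (0.032 and 0.41) and cell cycle genes 0.52 (0.0441 and 0.55). The NRF2 list did not pass without CD replicate 3 or 4 or MD+CA replicate 1 or 2. The acute phase median was 0.276 without MD+CA replicate 3, where the list still passed. T and NK cell markers did not pass without MD+CA replicate 2, at a median of 0.555, and the cell cycle list did not without CD replicate 1, 3 or 4 or MD+CA replicate 1, 2 or 4. Of the acute phase list 1 of 18 members rose, Saa3, and of the female-biased list 1 of 15 fell, Fmo2, with 9 and 5 when adjusted over the list alone. In the lists for T and NK cells, NRF2 and the cell cycle, 0 of 5, 13 and 12 members passed edgeR's test, 1, 6 and 4 had an unadjusted p under 0.05, and 1, 3 and 0 passed when adjusted over the list alone.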
